A study of Mus musculus with 24 samples.

How the data were processed

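Small RNA libraries were prepared from total RNA of mouse subcutaneous adipose tissue, purified with TRIzol, using the NEBNext small RNA kit, per the labels' protocols. The tissue was taken after 1 day, after 1 week and after 3 weeks of control or high-fat feeding. Each of the 6 diet-by-time groups held 4 libraries, 24 in all, and groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

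The deposited table held raw counts of reads for 1907 mature miRNA names, with the 5p and 3p arms counted separately, 1 column per library and no repeated name. FastQC, Trim Galore, Bowtie2 and featureCounts, with the mouse genome build mm10, were used upstream, per the submitters' processing notes. Versions, settings, the miRNA annotation and the treatment of reads with several genomic matches or in overlapping features are not given in the sources used here. Counts of miRNAs with several genomic copies, of near-identical family members and of overlapping miRNA genes are therefore uncertain. The unit was checked from the values, which were whole numbers with totals that differed between libraries. No name was a total or an unassigned class, and all columns matched a sample title.

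Of the 1907 names, 440 had 0 counts in every library. The filter filterByExpr of edgeR, with the 6 groups, a minimum count of 10 and a minimum total of 15, kept 558 miRNAs. The 1349 names left out held 0.0179% of the counts. Totals ranged from 1.99 to 16.3 M (mega-counts) per library, with a median of 5.30 M, so that a floor of 3 counts corresponded to 0.184 CPM (counts scaled to a library of 1 M) in the deepest library and 1.51 CPM in the shallowest. Reads carried no molecular identifiers that the sources mention, so intervals and floors based on counts cover counting error only. Pairs of libraries within a group were compared by a chi-square test of their counts. The lowest chi-square per degree of freedom was 172, so no pair matched within sampling noise and none was merged, which leaves open whether some libraries share an animal.

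Each comparison was a contrast in 1 cell-means model of the 6 groups, fitted to the counts of all 24 libraries with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, robust dispersion, Benjamini-Hochberg adjusted p under 0.05). The 8 comparisons were high-fat against control at each of the 3 times, the mean of these 3 contrasts, a joint test of whether the diet effect differed between times, the diet effect at week 3 minus that at day 1, and week 3 against day 1 in each diet. Fold changes are log2 with SE. The biological coefficient of variation was 0.359. A mean contrast of week 3 against day 1 over both diets was added after the data were seen. Levels are TMM-scaled CPM with the SD over 4 libraries.

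The lists of miRNAs comprised 12 named groups. These were the let-7 family, adipogenesis-promoting or adipocyte-enriched miRNAs, anti-adipogenic miRNAs, brown and beige adipocyte miRNAs, and inflammation and obesity-associated miRNAs. Further groups were miRNAs in introns of lipid metabolism or adipose expansion genes, the miR-17-92 cluster with its paralogues and the Dlk1-Dio3 imprinted cluster. The rest were the Sfmbt2 intron cluster, Hox cluster miRNAs, the miR-29 family and miRNAs made without Drosha or without DICER. The other 10 lists were markers of leukocytes, lymphocytes, erythrocytes, endothelium, smooth muscle and pericytes, fibroblasts, epithelium, skeletal muscle, neurons and liver. Some miRNAs belong to several lists. Of the 22 lists, 21 had 3 or more tested members and were tested with camera of limma 3.58.1, two-sided, at a preset correlation of 0.01. The test was repeated with a correlation estimated per list, and with fry. The miRNAs named in the text were the 12 with the smallest p in each direction among those past the threshold or, where fewer than 5 passed, the 5 with the smallest p in each direction. Added to these were members past the threshold when adjusted over the list alone (for the liver list, with 1 member, this is the unadjusted p), the 10 most abundant miRNAs, miR-451a and up to 3 abundant members of the other lists; the text gives a selection of them. Groups, comparisons, tests, lists, this rule and the first set of alternative settings below were fixed before the data were examined.

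Totals, detected miRNAs and the log2 ratio of miR-451a to the geometric mean of miR-144 and miR-486 (pseudocount 0.5 counts) were compared with exact two-sided permutation tests, 4 libraries against 4, for which the smallest possible p is 0.0286. A stratified test over the 3 times used all 343000 regroupings of diet within time. That first set comprised RLE size factors, library totals alone, size factors without the 5 most abundant miRNAs, no filter on low counts, a mean CPM of at least 10, DESeq2 1.42.0, limma-voom with sample quality weights, non-robust dispersion, a fit of the compared groups only, the replicate number as a block, an adjusted p under 0.1, an additional minimum of 1.5-fold, and each library left out in turn. For the lists it comprised an estimated correlation, fry and only the more abundant arm of each miRNA. Alternatives added after the data were seen used muscle and leukocyte marker means as covariates, or left out the 3 libraries lowest in leukocyte markers, the 3 highest in muscle markers, or 4 marker lists.

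The model was tested on simulated counts for the 558 miRNAs, in 5 runs. Each miRNA was drawn independently of the others, so the simulation lacks variation that miRNAs share, such as that of muscle or leukocyte content. Its recovery and false discovery rates may therefore not hold for the real libraries. With 0 changed miRNAs, there were 0 false calls per run at day 1 and 0.2 for the mean over the 3 times. With 200 changed miRNAs in the day 1 comparison, 20.6%, 53.7% and 91.2% of changes of 1.5-, 2- and 4-fold were recovered at a false discovery rate of 3.17%. With 20 changed miRNAs the shares were 2.86%, 28.6% and 70%. For the mean over the 3 times, 200 changed miRNAs gave 63.0%, 86.9% and 98.8% at a false discovery rate of 4.06%, and 20 changed miRNAs gave 17.1%, 82.9% and 96.7%. Gene positions are from GENCODE M21 on GRCm38.p6, the same assembly as mm10, where 549 of the 558 tested miRNAs matched a gene by name and 27 matched more than 1. A miRNA was placed in an exon where any annotated transcript of the host gene has an exon over it. It may lie in an intron of other transcripts of that gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.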

Results

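Mature microRNAs (miRNAs), short RNAs that repress messenger RNAs, were measured in subcutaneous adipose tissue, the white fat under the skin. Control and high-fat feeding were compared after 1 day, after 1 week and after 3 weeks, with 4 libraries in each of the 6 groups. The series title reports lower DICER, the enzyme that cuts most miRNA precursors, on the high-fat diet, and the comparisons ask which miRNAs differed between the diets and over time. The 24 libraries held 1.99 to 16.3 M miRNA counts (M, mega). The most abundant miRNA was miR-148a-3p, known to be enriched in adipocytes, at 16.7% of counts (chromosome 6, 51269812 to 51269910, intergenic; all positions are on GRCm38, the assembly called mm10). It was followed by miR-143-3p of smooth muscle and pericytes with 13.3% (chromosome 18, 61649196 to 61649258, intergenic) and endothelial miR-126a-3p with 8.75% (chromosome 2, 26591357 to 26591429, exon of Egfl7). Next came miR-99a-5p with 8.18% (chromosome 16, 77598936 to 77599000, intron of Mir99ahg) and miR-21a-5p, associated with inflammation, with 6.61% (chromosome 11, 86584067 to 86584158, exon of Vmp1).

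The total miRNA count was lower in the high-fat libraries. At day 1 it was 4.05 ± 1.495 M (SD, n = 4) on the high-fat diet against 7.25 ± 2.74 M on the control diet. At week 1 the means were 3.56 ± 0.760 and 9.24 ± 4.92 M, and at week 3 they were 5.88 ± 4.12 and 6.26 ± 1.03 M. The difference in log10 total was −0.262 at day 1, −0.381 at week 1 and −0.0885 at week 3, with exact two-sided permutation p of 0.0286, 0.0286 and 0.571 (adjusted over the 3 times, 0.0429, 0.0429 and 0.571); 0.0286 is the smallest p that 4 against 4 can give. Over the 3 times together the total was 42.97% lower, with an exact stratified permutation p of 0.00289 over 343000 regroupings. The number of miRNAs with 1 or more counts was 933.75 ± 87.6, 1009.5 ± 75.2 and 951.5 ± 64.7 in the control groups at the 3 times and 861 ± 62.8, 854 ± 66.6 and 899 ± 93.2 in the high-fat groups. The differences had exact permutation p of 0.229, 0.0571 and 0.343, and together they averaged −93.6 with an exact stratified permutation p of 0.00742. A library total depends on sequencing depth and is not a tissue level. Per the labels, 1 μg of total RNA entered each library, but read totals before counting are not given in the sources used here. Leaving out single libraries changed the day 1 total difference to between −0.310 and −0.169 (exact permutation p 0.0286 to 0.114) the week 1 difference to between −0.447 and −0.285 (0.0286 to 0.0571) and the week 3 difference to between −0.213 and −0.0182 (0.0571 to 0.886). The p exceeded 0.05 without any control replicate or without high-fat replicate 4 at day 1, and without any high-fat replicate at week 1. Every control total still lay above every high-fat total at both times. The lowest control and highest high-fat totals were 5.36 and 5.28 M at day 1, and 5.32 and 4.15 M at week 1. With 3 libraries against 4 the exact test has few regroupings, so these p-values cannot tell a weaker difference from a coarser test.

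**Figure D1:**
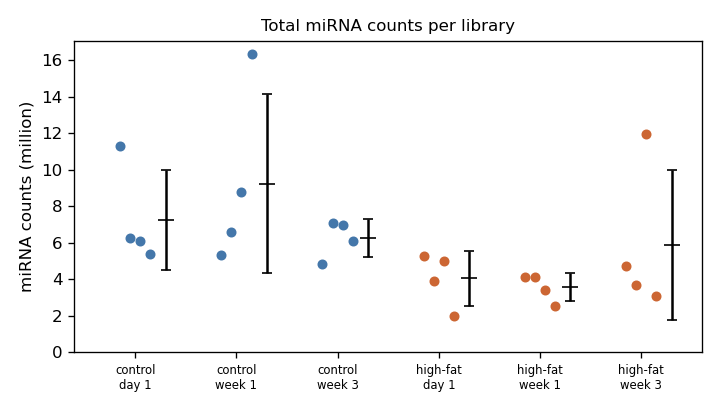
Total miRNA counts per library in M (y axis, from 0) for the 6 diet-by-time groups. Each point is 1 library and the black bars give the mean ± SD (n = 4); at week 1 the high-fat libraries lie between 2.54 and 4.15 M and the control libraries between 5.32 and 16.3 M.

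MiR-451a, a red cell miRNA that is cut by AGO2 and not by DICER (chromosome 11, 78073170 to 78073241, intergenic), did not differ detectably between the diets when set against miR-144 and miR-486, red cell miRNAs that need DICER (miR-486 is also known from muscle). The log2 ratio at day 1 was 3.60 ± 0.32 (SD, n = 4) on the control diet and 3.59 ± 0.40 on the high-fat diet. The corresponding values were 2.45 ± 0.64 and 2.68 ± 0.98 at week 1, and 2.77 ± 0.56 and 2.90 ± 0.24 at week 3. The differences of −0.01, 0.23 and 0.13 had exact permutation p of 0.943, 0.743 and 0.686 (adjusted p 0.943 each). They turned with single libraries left out, running from −0.21 to 0.14, from −0.13 to 0.62 and from −0.08 to 0.36. Over the 3 times the difference was 0.12, with an exact stratified permutation p of 0.613. As far as these miRNAs come from red cells, the ratio cannot show a change of DICER in other cells of the tissue.

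Markers of other tissues varied widely between libraries of the same group. The mean log2 CPM of the 8 skeletal muscle miRNAs, among them miR-1a-3p, miR-133b-3p and miR-206-3p, spanned 8.82 log2 units over the 24 libraries, with a pooled SD within groups of 2.16. The 12 leukocyte marker arms, among them miR-142a-3p, miR-150-5p and miR-223-3p, spanned 2.52 log2 units with an SD of 0.67. Muscle markers were highest in high-fat week 1 replicate 2 (9.45), control week 1 replicate 4 (8.27) and control week 3 replicate 1 (8.19). Leukocyte markers were lowest in high-fat week 1 replicate 3 (6.27), control week 3 replicate 1 (6.46) and high-fat week 1 replicate 1 (6.49). The first principal component of the 558 tested miRNAs held 34.2% of the variance, with muscle miRNAs such as miR-1a-3p and miR-133b-3p leading its loadings, and the second held 17.5%. Neither separated the 6 groups (permutation p 0.152 and 0.125).

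**Figure D2:**
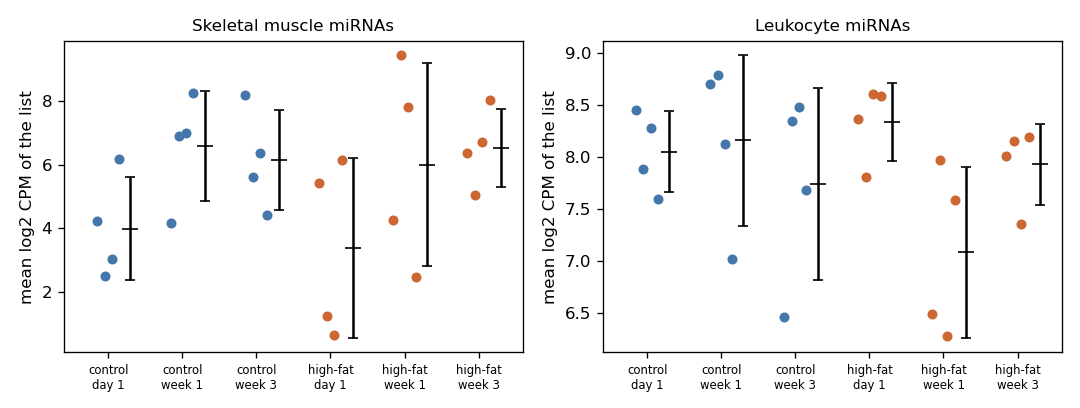
Mean log2 CPM of the skeletal muscle markers (left) and the leukocyte markers (right) per library in the 6 diet-by-time groups. Each point is 1 library and the black bars give the mean ± SD (n = 4); the muscle mean runs from 0.63 to 9.45 and the leukocyte mean from 6.27 to 8.79.

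After 1 day on the diets, the abundant miRNAs differed little between high-fat and control libraries (4 against 4). MiR-148a-3p had a log2 fold change of −0.14 ± 0.24 (SE), miR-143-3p 0.35 ± 0.23, miR-126a-3p −0.14 ± 0.15, miR-21a-5p −0.14 ± 0.18 and miR-451a −0.51 ± 0.30. No miRNA of 558 passed an adjusted p of 0.05 with edgeR, DESeq2 or limma-voom, each with a count of 0; 17 had an unadjusted p under 0.05 in edgeR (7 higher, 10 lower), where 27.9 are expected by chance. Among the smallest p were higher values for miR-30e-3p (0.47 ± 0.19), miR-3068-3p (0.67 ± 0.27), miR-677-5p (1.49 ± 0.60), miR-363-5p (1.58 ± 0.66) and miR-345-3p (0.41 ± 0.18). Lower values were found for miR-190a-5p (−0.71 ± 0.26), miR-99a-3p (−0.62 ± 0.24), miR-136-5p (−1.05 ± 0.41) and miR-322-5p (−0.40 ± 0.17), each with an adjusted p of 0.982. MiR-9-5p also had a small p, but at 0.0438 ± 0.0876 CPM (SD, n = 4) on the high-fat diet it was under the counting floor there, so no fold is given. Single libraries carried several of these values: without high-fat replicate 4, miR-677-5p had 0.14 and miR-3068-3p 0.34. MiR-190a-5p had −0.47 without control replicate 4, miR-99a-3p −0.39 without high-fat replicate 3 and miR-363-5p 2.41 without control replicate 1. MiR-363-5p was at or under the counting floor in control replicates 2 and 4, at 0.431 and 0.398 CPM. MiR-143-3p had 0.17 without control replicate 2 and 0.75 without control replicate 3. Of 21 lists, 4 passed camera. Members of the Sfmbt2 intron cluster, a rodent cluster in an imprinted gene, were higher in 9 of 9 (median log2 fold change 0.54, adjusted p 0.0049, and adjusted p = 0.755 with an estimated correlation). Erythrocyte markers were lower in 6 of 6 (median −0.57, adjusted p 0.00945, and adjusted p = 0.686 with an estimated correlation). In the miR-17-92 cluster and its paralogues, known to promote proliferation, 16 of 22 were higher (median 0.13), and in the Dlk1-Dio3 imprinted cluster, expressed from the maternal chromosome 12, 52 of 73 were lower (median −0.15; adjusted p 0.0398 each, and adjusted p = 0.755 with an estimated correlation). Leukocyte markers were higher in 9 of 12 (median 0.31, adjusted p 0.18). Control replicate 4 had the lowest mean log2 CPM of both the leukocyte markers (7.59) and the Sfmbt2 cluster (2.20) at day 1, and high-fat replicates 3 and 4 had the highest of both (8.61 and 8.58, and 4.15 and 4.05). No member of the 4 lists passed when adjusted over the list alone. Without control replicate 4 none of the lists passed and the Dlk1-Dio3 median was 0.02; without high-fat replicate 3 there was 1 list, and without high-fat replicate 4 there were 2, and without high-fat replicate 2 there were 6. With the muscle and leukocyte means as covariates 0 lists passed.

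After 1 week, leukocyte miRNAs were lower on the high-fat diet, without any single miRNA passing over all tested. MiR-142a-3p of all leukocytes was at 3084 ± 2454 CPM (SD, n = 4) against 9455 ± 5107 CPM on the control diet, a log2 fold change of −1.62 ± 0.61 (SE). The lymphocyte miRNA miR-150-5p was at 1981.3 ± 1502 against 5774 ± 2729 CPM (−1.54 ± 0.58), and miR-342-3p had −1.09 ± 0.40. Of the 12 leukocyte marker arms 10 were lower (median −1.20, adjusted p 5.61e-05, and adjusted p = 0.551 with an estimated correlation), and 4 passed when adjusted over the list alone (miR-142a-3p, miR-342-3p, miR-150-5p and miR-150-3p). Members of the Sfmbt2 intron cluster were lower in 9 of 9 (median −1.11, adjusted p 0.000345, and adjusted p = 0.551 with an estimated correlation), and 5 passed when adjusted over the list alone. These were miR-467c-5p (−1.25 ± 0.49), miR-467d-5p (−1.20 ± 0.43), miR-467e-5p (−1.07 ± 0.41), miR-669c-5p (−1.11 ± 0.44) and miR-669o-5p (−1.23 ± 0.43). In the miR-17-92 cluster and its paralogues 21 of 22 were lower (median −0.46, adjusted p 6.84e-07, and adjusted p = 0.551 with an estimated correlation). Of these, miR-18b-5p (chromosome X, 52742331 to 52742413, intergenic) passed when adjusted over the list alone. Its level was 3.998 ± 1.632 CPM on the control diet. On the high-fat diet it was 0.372 ± 0.438 CPM, at or under the counting floor in each library, so no fold is given.

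Also at week 1, all 73 members of the Dlk1-Dio3 imprinted cluster were higher on the high-fat diet (median 0.60, adjusted p 1.61e-25, and adjusted p = 0.382 with an estimated correlation). Examples were miR-369-3p (0.82 ± 0.28), miR-485-3p (0.94 ± 0.33) and miR-382-5p (0.72 ± 0.25), and none passed when adjusted over the list alone. Without high-fat replicate 2, miR-369-3p had 0.50. Epithelial markers were higher in 16 of 17 (median 0.46, adjusted p 0.00194, and adjusted p = 0.652 with an estimated correlation), including miR-205-5p of skin and gland epithelium (1.66 ± 0.57, or 1.08 without high-fat replicate 1). The liver miRNA miR-122-5p had 1.36 ± 0.50 (unadjusted p 0.0133 and adjusted p 0.225 in edgeR). Further miRNAs with small p were miR-224-5p (0.61 ± 0.22), miR-1941-5p (−1.80 ± 0.53), miR-488-3p (−1.69 ± 0.56) and miR-7a-5p (−1.26 ± 0.42), each with an adjusted p of 0.225. MiR-1941-5p was near the counting floor on the high-fat diet, at 0.424 to 1.706 CPM. MiR-3076-5p was also lower (adjusted p 0.225 in edgeR). Its high-fat mean of 0.390 ± 0.454 CPM was under the counting floor there, so no fold is given. In contrast, miR-148a-3p had −0.01 ± 0.24, miR-21a-5p −0.26 ± 0.18 and miR-451a 0.36 ± 0.30. With edgeR 0 miRNAs passed, with 79 at an unadjusted p under 0.05 (28 higher, 51 lower); DESeq2 called 0 and limma-voom with sample quality weights called 17, of which 16 were lower. Of those 17, 5 were leukocyte markers, 6 belonged to the miR-17-92 list and 4 to the Sfmbt2 list. Without the 3 libraries highest in muscle markers (high-fat week 1 replicate 2, control week 1 replicate 4 and control week 3 replicate 1), edgeR called 67 (25 higher, 42 lower), of which 14 were in the Dlk1-Dio3 cluster and 9 were leukocyte markers. That choice itself widens the leukocyte difference. Control week 1 replicate 4 had the lowest leukocyte mean of its group (7.01) and high-fat week 1 replicate 2 the highest of its group (7.97). Without the 3 libraries lowest in leukocyte markers (high-fat week 1 replicates 1 and 3 and control week 3 replicate 1), a choice that itself shrinks the leukocyte difference, only 2 lists passed, Dlk1-Dio3 (median 0.51) and miR-17-92 (−0.43). The leukocyte median was −0.65, the Sfmbt2 median −0.60 and the epithelial median 0.09. The epithelial call was also lost without high-fat replicate 1 alone (median 0.29, adjusted p 0.464). With the muscle and leukocyte means as covariates, which take up the leukocyte difference by construction, only Dlk1-Dio3 passed (median 0.31), and the miR-17-92 median was −0.08.

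After 3 weeks, no list passed among the 21 tested and no miRNA passed. The lowest p was that of let-7i-3p, the minor arm of a let-7 family member (−0.54 ± 0.17 SE, n = 4 per diet), followed by miR-129-2-3p (−1.38 ± 0.47), which alone of the 6 neuronal arms passed when adjusted over the list alone. Other lower values were those of miR-3102-3p.2-3p (−0.88 ± 0.35), miR-190b-5p (−0.52 ± 0.22) and miR-1941-5p (−1.11 ± 0.51). Higher values were those of miR-452-5p (0.67 ± 0.27), miR-877-3p (0.89 ± 0.37), miR-217-5p (0.93 ± 0.44), miR-92a-1-5p (1.07 ± 0.53) and miR-222-5p (0.52 ± 0.27). MiR-877-3p had 0.39 without high-fat replicate 4 and miR-92a-1-5p 0.51 without high-fat replicate 1, and miR-1941-5p ran from −2.06 without high-fat replicate 2 to −0.66 without high-fat replicate 3. Leukocyte markers were higher in 7 of 12 (median 0.03, adjusted p 0.528) and epithelial markers lower in 15 of 17 (median −0.31, adjusted p 0.081). MiR-148a-3p had 0.08 ± 0.24 and miR-451a −0.20 ± 0.30. EdgeR, DESeq2 and limma-voom each called 0 miRNAs, with 10 at an unadjusted p under 0.05 in edgeR (3 higher, 7 lower). With single libraries left out, the 10 became 5 (without high-fat replicate 1) to 28 (without control replicate 1). In edgeR, the 95% interval lay within 2-fold for 65.1% of the 558 miRNAs. List counts depended on single libraries, with 2 lists without control replicate 1, 4 without control replicate 2, 4 without control replicate 3 and 1 without high-fat replicate 3.

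**Figure D3:**
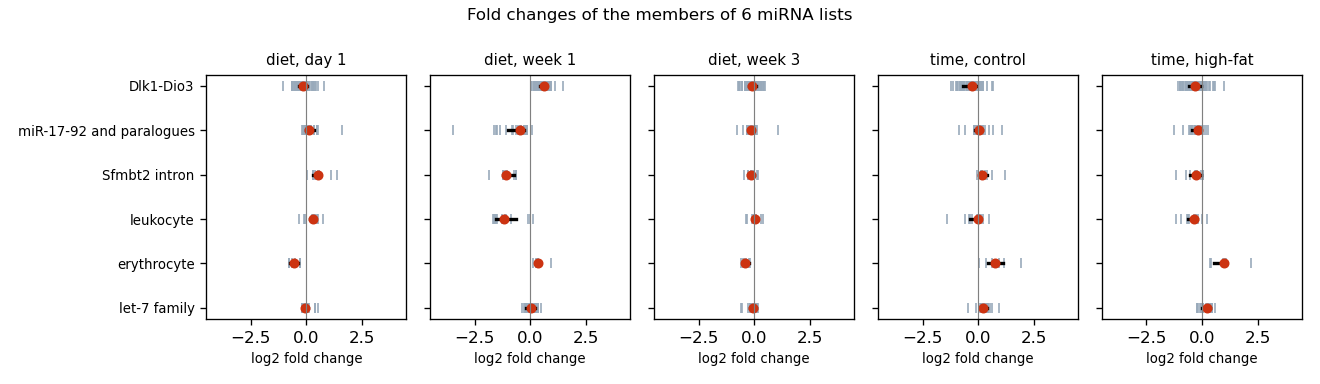
Log2 fold changes (x axis) of the members of 6 miRNA lists for high-fat against control at the 3 times and for week 3 against day 1 in each diet. Ticks are single members, the black line spans their quartiles and the red dot is their median; at week 1 the Dlk1-Dio3 median is 0.60 and the leukocyte median is −1.20.

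Averaged over the 3 times (12 high-fat against 12 control libraries), no miRNA passed and the estimates were close to 0 for most. MiR-1941-5p (−0.98 ± 0.30 SE), miR-1941-3p (−0.87 ± 0.30), let-7i-3p (−0.30 ± 0.10), miR-190b-5p (−0.38 ± 0.13) and miR-18b-5p (−1.23 ± 0.46) had the smallest p among lower miRNAs. Among higher miRNAs these were miR-122-5p of liver (0.65 ± 0.29, adjusted p 0.993), miR-667-3p (0.40 ± 0.19), miR-125b-1-3p (0.23 ± 0.11), miR-431-3p (0.43 ± 0.21) and miR-335-3p (0.65 ± 0.31). MiR-451a was at −0.12 ± 0.17. MiR-1941-5p and miR-18b-5p were near or under the counting floor in some libraries. EdgeR, DESeq2 and limma-voom each called 0, with 18 at an unadjusted p under 0.05 in edgeR (5 higher, 13 lower), and the 95% interval lay within 2-fold for 89.4% of the 558. Without high-fat week 3 replicate 2 edgeR called 3 (miR-1941-5p, miR-1941-3p and miR-203-5p, all lower).

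Across lists, the mean diet contrast had the Dlk1-Dio3 cluster higher in 60 of 73 (median 0.13, adjusted p 2.56e-10) and the miR-17-92 list lower in 20 of 22 (median −0.19, adjusted p 0.00238), with adjusted p = 0.999 with an estimated correlation for both. Taken by time, the Dlk1-Dio3 cluster was higher in 73 of 73 at week 1 (median 0.60), but lower in 52 of 73 at day 1 (−0.15) and in 46 of 73 at week 3 (−0.11), with an exact permutation p of 0.101 for week 1 against day 1 (adjusted p 0.666). The miR-17-92 list was lower in 21 of 22 at week 1 (−0.46) and 18 of 22 at week 3 (−0.14), but higher in 16 of 22 at day 1 (0.13), with an exact permutation p of 0.0167 for week 1 against day 1 (adjusted p 0.251). The miR-17-92 call was lost without any of 6 libraries (control day 1 replicate 1, control week 1 replicate 2, control week 3 replicates 2 and 3, high-fat day 1 replicate 2 and high-fat week 3 replicate 3), with adjusted p of 0.0509 to 0.14. The other lists did not pass. Median log2 fold changes were −0.01 for the let-7 family, −0.06 for adipogenesis-promoting, −0.04 for anti-adipogenic and −0.03 for brown and beige adipocyte miRNAs. They were −0.10 for inflammation and obesity-associated miRNAs and −0.09 for miRNAs in introns of lipid metabolism or adipose expansion genes. The Sfmbt2 cluster had −0.21, Hox cluster miRNAs −0.04, the miR-29 family −0.19 and miRNAs made without Drosha or without DICER −0.05. Among cell type markers the medians were −0.24 for leukocytes, −0.02 for lymphocytes, −0.12 for erythrocytes, 0.002 for endothelium, −0.06 for smooth muscle and pericytes and 0.02 for fibroblasts. They were −0.01 for epithelium, 0.14 for skeletal muscle and −0.03 for neurons. The test leaned up for the lymphocyte list, whose median and mean (−0.04) were negative, and for the epithelial list, whose mean was 0.05.

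Whether the diet effect depended on time was tested directly. The diet effect at week 3 minus that at day 1 was positive for miR-452-5p (1.06 ± 0.37 SE, 4 libraries in each of the 4 groups), miR-29b-1-5p (1.47 ± 0.65), miR-30a-5p (0.51 ± 0.23) and miR-190a-5p (0.78 ± 0.37). It was negative for miR-677-5p (−2.27 ± 0.84), miR-345-3p (−0.67 ± 0.25), miR-363-5p (−2.36 ± 0.95), miR-3068-3p (−0.84 ± 0.37) and miR-425-3p (−0.66 ± 0.30), each with an adjusted p of 0.991. Without high-fat day 1 replicate 4, miR-677-5p had −0.92 and miR-3068-3p −0.52, and miR-29b-1-5p had 0.93 without high-fat week 3 replicate 2. MiR-363-5p was at or under the counting floor in control day 1 replicates 2 and 4 and in control week 3 replicate 1. EdgeR, DESeq2 and limma-voom each called 0 miRNAs, with 11 at an unadjusted p under 0.05 in edgeR. In the joint test over the 3 times the smallest p belonged to miR-369-3p, miR-425-3p, miR-136-5p, miR-363-5p, miR-224-5p, miR-18b-5p and miR-7a-5p, with a lowest adjusted p of 0.567. The 3 tools each called 0 there too, with 41 at an unadjusted p under 0.05 in edgeR. No list passed for week 3 minus day 1, and 3 passed without control day 1 replicate 1, without control week 3 replicate 1 or without high-fat day 1 replicate 2, and 1 without high-fat week 3 replicate 1. In permutation tests of the list means against the day 1 diet effect, the 3 smallest p were at week 1. They belonged to the miR-17-92 list (−0.94, exact permutation p 0.0167), the lymphocyte markers (−0.55, exact permutation p 0.0171) and the Sfmbt2 cluster (−1.81, exact permutation p 0.018), with an adjusted p of 0.251 each.

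Between day 1 and week 3 on the control diet, miR-322-5p and miR-452-5p fell. MiR-322-5p, the mouse counterpart of human miR-424 (chromosome X, 53054255 to 53054349, intergenic), went from 385 ± 62.7 CPM (SD, n = 4) at day 1 to 206.2 ± 14.0 at week 1 and 222.5 ± 62.1 at week 3. Its week 3 to day 1 log2 fold change was −0.79 ± 0.17 (SE; adjusted p 0.0288). MiR-452-5p (chromosome X, 72262224 to 72262308, intron of Gabre) went from 9.63 ± 2.47 to 5.41 ± 1.40 and 4.04 ± 0.671 CPM, with −1.24 ± 0.26 (adjusted p 0.0288). On the high-fat diet the levels at the 3 times were 292 ± 17.1, 228 ± 27.01 and 220.5 ± 21.5 CPM for miR-322-5p and 7.26 ± 1.64, 5.23 ± 0.487 and 6.50 ± 2.05 CPM for miR-452-5p. Next were miR-369-3p of the Dlk1-Dio3 cluster (−1.21 ± 0.28, adjusted p 0.051), which passed when adjusted over the list alone, miR-344b-3p (−1.94 ± 0.53) and miR-350-3p (−0.84 ± 0.24). At week 3, miR-344b-3p was at 0 to 1.454 CPM, near or under the counting floor in some libraries. Higher values were those of miR-23b-5p (1.11 ± 0.31), miR-345-3p (0.64 ± 0.18), let-7b-3p (0.94 ± 0.27), let-7d-5p (0.56 ± 0.16) and miR-674-3p (0.68 ± 0.21).

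EdgeR called 2 miRNAs in this control time contrast, with 83 at an unadjusted p under 0.05 (42 higher, 41 lower), while DESeq2 called 6 and limma-voom 4. Both calls were lost without day 1 replicate 2 (adjusted p 0.104) or 3 (0.107) and without week 3 replicate 1 (0.142) or 2 (0.124). Without week 3 replicate 3 miR-452-5p had 0.0639 and miR-322-5p 0.178, and without week 3 replicate 4, where 1 call remained, miR-452-5p had 0.0531. Both were also lost without a filter on low counts, in a fit of the compared groups only, without the 3 libraries lowest in leukocyte markers (0.218) and without the 3 highest in muscle markers. Members of the Dlk1-Dio3 cluster were lower at week 3 in 60 of 73 (median −0.28, adjusted p 4.64e-10, and adjusted p = 0.627 with an estimated correlation). Let-7 family members, known to rise as tissues mature, were higher in 20 of 22 (median 0.23, adjusted p 0.0118, and adjusted p = 0.627 with an estimated correlation), and let-7d-5p and let-7b-3p passed when adjusted over the list alone. That call was lost without day 1 replicate 4 (adjusted p 0.0537) or week 3 replicate 4 (0.0594). Skeletal muscle markers were higher in 8 of 8 (median 2.10, adjusted p 0.0356, and adjusted p = 0.726 with an estimated correlation). Without week 3 replicate 1 the muscle median was 0.70 (adjusted p 0.201), and the call was also lost without day 1 replicate 1 (0.0827), 2 (0.115) or 3 (0.0713). Without week 3 replicate 3, 6 lists passed in place of 3.

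**Figure D4:**
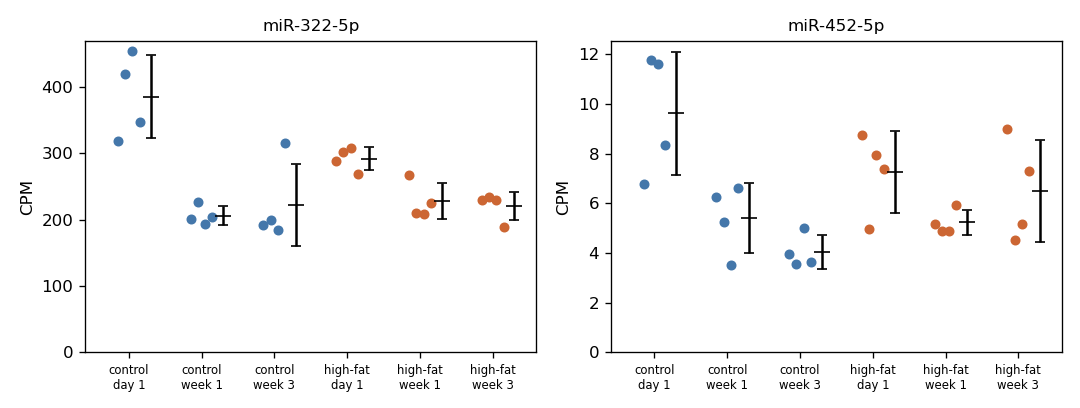
Levels in CPM (y axes, from 0) of miR-322-5p (left) and miR-452-5p (right) per library in the 6 diet-by-time groups. Each point is 1 library and the black bars give the mean ± SD (n = 4); in control libraries miR-322-5p averages 385 CPM at day 1 and 222.5 CPM at week 3.

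On the high-fat diet, no miRNA passed between day 1 and week 3 with edgeR, though several were just above the threshold. MiR-143-5p, the minor arm of a smooth muscle miRNA (chromosome 18, 61649196 to 61649258, intergenic), had 0.82 ± 0.18 (SE, n = 4 per time). MiR-504-5p (chromosome X, 59097658 to 59097736, intron of Fgf13) had 1.54 ± 0.35 and miR-139-5p (chromosome 7, 101475376 to 101475443, intron of Pde2a) 0.76 ± 0.18, each with an adjusted p of 0.0532. Other higher values were let-7d-5p (0.58 ± 0.16) and miR-744-5p (0.64 ± 0.19), and lower values were miR-677-3p (−2.85 ± 0.77), miR-186-5p (−1.16 ± 0.32), miR-450b-5p (−0.74 ± 0.22), miR-350-3p (−0.82 ± 0.24) and miR-351-5p (−0.79 ± 0.24). Adjusted over the list alone, miR-143-5p, let-7d-5p, endothelial miR-126a-3p (0.48 ± 0.15) and miR-335-3p of an intron of Mest (1.81 ± 0.56, or 1.07 without week 3 replicate 3) passed. Dlk1-Dio3 members were lower in 57 of 73 (median −0.30, adjusted p 5.05e-05, and adjusted p = 0.802 with an estimated correlation). Muscle markers were higher in 8 of 8 (median 2.20, adjusted p 0.0041, and adjusted p = 0.802 with an estimated correlation), and erythrocyte markers in 6 of 6 (median 0.98, adjusted p 0.0041, and adjusted p = 0.612 with an estimated correlation). The count of 0 in edgeR stood beside 88 at an unadjusted p under 0.05 (53 higher, 35 lower), 11 called by DESeq2 and 14 by limma-voom. It was 2 without day 1 replicate 2 and 1 without week 3 replicate 2, and 9 with the muscle and leukocyte means as covariates. The 3 lists became 6 without day 1 replicate 2, and 5 without week 3 replicate 1 or without week 3 replicate 4.

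**Figure D5:**
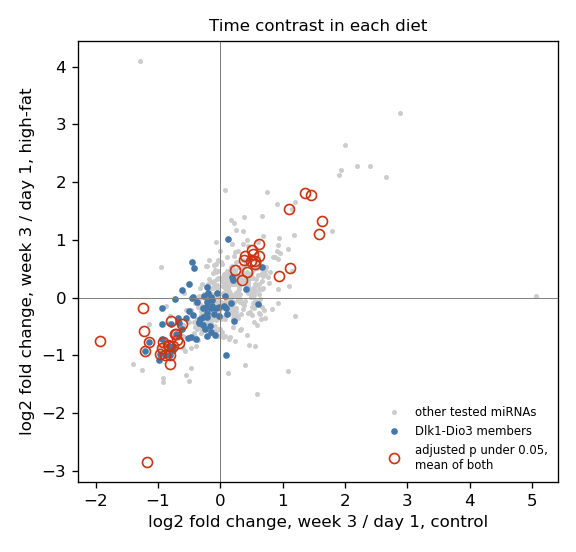
Log2 fold change of week 3 against day 1 in control (x axis) and high-fat (y axis) libraries for the 558 tested miRNAs. Blue points are the 73 members of the Dlk1-Dio3 cluster and red circles are the 40 miRNAs with an adjusted p under 0.05 for the mean of both contrasts, a comparison chosen after the data were seen; Spearman's rho across miRNAs, which are not independent replicates, is 0.594.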

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

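The tests of miR-451a, read number, muscle correlation and the leukocyte markers were chosen, and the readings of the other splits of the libraries were set, after the results had been seen; the thinning to a common depth was set before its outcome was known. The 4 libraries that stood far from the rest of their group were found among 90 sets of 4 values, where chance gives 4.5. The endothelial marker mean (log2 CPM) was 8.15 in high-fat week 1 replicate 2, against 9.41 to 9.50 in the other libraries of its group. The smooth muscle and pericyte mean was 11.999 in control day 1 replicate 3, against 11.67 to 11.73. The log2 CPM of miR-322-5p was 8.30 in control week 3 replicate 4, against 7.53 to 7.64, and 7.56 in high-fat week 3 replicate 4, against 7.84 to 7.87.

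The total miRNA count was 42.97% lower in the high-fat libraries, or −0.81 on the log2 scale. If DICER-dependent miRNAs had fallen by that amount at an unchanged red cell content, the share of miR-451a would be higher by 0.81, but its log2 fold change over the 3 times was −0.12 (95% interval −0.47 to 0.24, adjusted p 0.993 in edgeR, higher in 1 of 3 times), which argues against this explanation. The lower number of detected miRNAs (−93.6, exact permutation p 0.00742) shrank to −19.5 (exact permutation p 0.0736) when every library was thinned to 1.99 M counts in 20 draws, in line with lower depth. Fewer reads sequenced or loaded per library cannot be told apart from fewer miRNA molecules, since read totals before counting are not given in the sources used here and the exact permutation p of 0.00289 for the miRNA total holds for either. Other effects of the diet on miRNA output, such as one beside a changed red cell content, stay open.

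Skeletal muscle miRNAs varied within groups with an SD of 2.16 log2 units. After centring on group means, miR-1a-3p, miR-133a-3p, miR-133b-3p and miR-206-3p varied together over the 24 libraries. The lowest of their 6 pairwise Spearman rho was 0.883 (miR-1a-3p and miR-206-3p; Pearson's r 0.859, permutation p 1e-05 for both, the smallest the resamples can give; r 0.824 without the 2 libraries farthest from the median), which is consistent with skeletal muscle in some of the dissected samples. Counting noise, which is independent between miRNAs, is argued against as the whole cause by the same rho. The higher muscle markers at week 3 in both diets may thus reflect dissection, and an effect of age on muscle miRNAs in fat was not tested.

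At week 1 the leukocyte markers were lower on the high-fat diet (median −1.20). If all leukocytes were fewer, miR-223-3p of myeloid cells should be lower as well, but it was 0.16 higher (exact permutation p 0.457) while the mean of miR-142a-3p, miR-150-5p and miR-155-5p was −1.70 (exact permutation p 0.114), and the difference of 1.86 had an exact permutation p of 0.0857, which decides nothing with 4 against 4. Without high-fat replicates 1 and 3 the median was −0.66 (adjusted p 0.305), but these 2 were picked for the lowest values of the same markers, so a smaller difference was bound to follow. The lymphocyte list, of miR-150 and the miR-181 family, decides nothing: 6 of 10 were higher (median 0.08, adjusted p 0.692), while its mean log2 CPM differed by −0.33 (exact permutation p 0.0571, adjusted p 0.377). Less lymphoid tissue, such as a lymph node, in some samples cannot be told apart from an effect of the diet, since miR-181 is also known from other tissues.

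A count of 0 is reached by every split, so the counts of 0 miRNAs past the threshold in edgeR decide nothing about chance. This holds at day 1, week 1 and week 3 (35 of 35 splits; highest others 1, 78 and 5), for the mean over the 3 times, the joint test and week 3 minus day 1 (100 of 100 drawn splits; highest others 15, 19 and 2) and for the high-fat time contrast (35 of 35, highest other 2). It also holds for the 0 lists at week 3 (35 of 35, highest other 9) and for week 3 minus day 1 (100 of 100, highest other 7). The week 1 split with 78 miRNAs points to a structure of the samples, and what that split separates was not tested.

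At an unadjusted p under 0.05, chance could not be excluded for any diet comparison. The counts were 17 at day 1 (14 of 35 splits gave as many, highest other 56), 79 at week 1 (5 of 35, highest other 160), 10 at week 3 (29 of 35, highest other 76), 18 for the mean (58 of 100, highest other 111), 41 for the joint test (18 of 100, highest other 151) and 11 for week 3 minus day 1 (70 of 100, highest other 66). Between day 1 and week 3, the count of 88 in the high-fat contrast was reached by 1 of 35 splits, the real one (highest other 68). This argues against chance for the count but does not exclude it. It is the smallest share that 35 splits can give, and the comparisons were read without a correction for their number. Chance could not be excluded for the 83 of the control contrast (3 of 35, highest other 84) or the 2 past the threshold there (3 of 35, highest other 4). Chance could not be excluded for the lists past the threshold, 4 at day 1 (14 of 35 splits, highest other 7), 5 at week 1 (16 of 35, highest other 8), 2 for the mean (85 of 100, highest other 8), 3 in the control time contrast (25 of 35, highest other 7) and 3 in the high-fat one (15 of 35, highest other 5).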

How the results depend on the processing

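The alternatives with marker covariates, with libraries left out for their muscle or leukocyte markers, with 4 marker lists left out, and the mean time contrast over both diets were chosen after the data were seen; the others were planned. Among values of single miRNAs and lists, 15507 comparisons with an alternative stayed on their side of the threshold without a marked shift, 164 lost the call, 151 gained one, 153 moved and 3 turned, the cause of which was not tested. No diet comparison had a miRNA past the threshold in the main fit. The miRNAs of those comparisons could not lose a call, so the 15507 does not measure how well calls held. The 3 that turned did so with the covariates. They were the Dlk1-Dio3 imprinted cluster, high-fat against control at day 1 (median 0.00323, adjusted p 0.760); the Sfmbt2 intron cluster, high-fat against control at week 1 (median −0.10, with the test leaning up); and epithelial markers (mammary duct or skin), high-fat against control at week 1 (median 0.0329, with the test leaning down). Counts of miRNAs for the diet at day 1, at week 3, for the joint test and for week 3 minus day 1 stayed at 0 throughout. At week 1 the count was 17 with limma-voom and 67 without the 3 muscle-rich libraries. The control time contrast (2) gave 0 without a filter, with the replicate block, with only the compared groups and without the leukocyte-poor or the muscle-rich libraries, 1 at a mean CPM of at least 10, 6 with DESeq2, 4 with limma-voom and 14 with covariates. The high-fat time contrast (0) gave 3 without the 5 most abundant miRNAs in the library size, at a mean CPM of at least 10, without the muscle-rich libraries and at an adjusted p under 0.1, 1 without a filter and without the leukocyte-poor libraries, 2 with only the compared groups, 11 with DESeq2, 14 with limma-voom and 9 with covariates. The mean time contrast (40) gave 19 without a filter, 71 with DESeq2, 91 with limma-voom, 76 with covariates, 22 without the leukocyte-poor libraries and 98 at an adjusted p under 0.1. All 17 list calls were lost with an estimated correlation and with fry, which left 0 in each comparison. List counts with covariates were 0 at day 1 (from 4), 1 at week 1 (from 5), 1 for the mean (from 2) and 1 for the high-fat time contrast (from 3). Without the leukocyte-poor libraries they were 2 at week 1, 2 at week 3 (from 0), 4 for week 3 minus day 1 (from 0) and 5 for the high-fat time contrast, and without the muscle-rich libraries 2 at week 3, 4 for the mean, 4 for week 3 minus day 1 and 5 for the high-fat time contrast. With only the more abundant arm they were 2 at day 1, 2 at week 3 and 1 for the control time contrast. With each library left out in turn, miRNA counts ran from 0 to 3 for the mean diet contrast, 0 to 3 for the control, 0 to 2 for the high-fat and 19 to 45 for the mean time contrast, where the count was 19 without control week 3 replicate 1, 25 without high-fat day 1 replicate 1 and 24 without high-fat week 3 replicate 4. List counts ran from 0 to 6 at day 1, 5 to 7 at week 1, 0 to 4 at week 3, 1 to 3 for the mean, 0 to 3 for week 3 minus day 1, 2 to 6 for the control and 3 to 6 for the high-fat time contrast. The difference in log10 totals ran from −0.310 to −0.169 at day 1, −0.447 to −0.285 at week 1 and −0.213 to −0.0182 at week 3, and that in detected miRNAs from −98.4 to −30.0, −185.7 to −126.7 and −98.5 to −31.5. The miR-451a ratio ran from −0.21 to 0.14, −0.13 to 0.62 and −0.08 to 0.36. With 10 or more counts the week 1 difference in detected miRNAs was −105.75 (exact permutation p 0.0286). The replicate numbers did not pair the samples consistently. Of the 4 pairs of each diet comparison, 3 correlated above 0.1 at day 1, 3 at week 1 and 1 at week 3. In the time contrasts 0 did so in control and 2 in high-fat mice. For 7 of 24 libraries, the mean correlation with libraries of other groups was highest for their own number. Whether the numbers pair samples at day 1 or week 1 stays open. As a block, the replicate numbers gave 0 control time calls and 2 day 1 lists. Sign-flip tests of the totals, −0.262 at day 1 and −0.381 at week 1, could not pass the threshold with 4 differences. No scaling moved a median over all miRNAs by more than 0.1. Summing repeated names and leaving out libraries under 20% of the median total were not run, since no name repeated and the lowest total was 37.6% of the median. Depth limits the rarer miRNAs, with a floor of up to 1.51 CPM.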

Other observations

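The comparison of week 3 with day 1 over both diets, its fit with covariates, the overlap of the diets, the Dlk1-Dio3 test between times and the test on miRNAs with several genomic copies were all chosen after the data were seen. Averaged over both diets (8 libraries against 8), 40 of 558 miRNAs passed an adjusted p of 0.05 in edgeR between day 1 and week 3, 19 higher and 21 lower. Among the higher were miR-504-5p (1.32 ± 0.24 SE), miR-143-5p (0.67 ± 0.13), miR-139-5p (0.64 ± 0.12) and let-7d-5p (0.57 ± 0.12), each with an adjusted p of 0.00502, as well as miR-744-5p (0.60 ± 0.13), endothelial miR-126a-3p (0.36 ± 0.11, adjusted p 0.0473) and the erythrocyte miRNA miR-144-3p (0.78 ± 0.24, adjusted p 0.0478). In all, 4 of the 22 let-7 family arms passed. Among the lower were miR-322-5p (−0.60 ± 0.12), miR-450b-5p (−0.72 ± 0.15) and miR-351-5p (−0.73 ± 0.17), 3 of the 11 arms of a cluster on chromosome X, and miR-350-3p (−0.83 ± 0.17). Of the 73 Dlk1-Dio3 members 62 were lower (median −0.31) and 8 passed, all lower, including miR-369-3p (−1.07 ± 0.20; chromosome 12, 109743418 to 109743496, exon of Mirg), miR-376c-3p (−0.80 ± 0.20) and miR-495-3p (−0.83 ± 0.21). The count was 19 without control week 3 replicate 1, 25 without high-fat day 1 replicate 1, 24 without high-fat week 3 replicate 4 and 22 without the 3 libraries lowest in leukocyte markers, with 71 called by DESeq2 and 91 by limma-voom.

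Of the lists, Dlk1-Dio3 was lower (adjusted p 6.38e-09), and let-7 (0.0118), erythrocyte (0.00655) and muscle markers (0.00492) were higher, each with adjusted p = 0.664 with an estimated correlation. The erythrocyte call ended with the muscle and leukocyte means as covariates (adjusted p 0.229), where the median went from 0.88 (quartiles 0.49 to 1.10) to 0.38 (0.30 to 0.48). Its miR-486 arms, also known from muscle, shrank (miR-486a-5p from 0.98 ± 0.31 to 0.28 ± 0.23), while miR-144-3p did not (0.88 ± 0.24, adjusted p 0.0242). The let-7 list had an adjusted p of 0.0107 with the covariates, and adjusted p = 0.805 with an estimated correlation as well, and the muscle call ended by construction (0.988). With these covariates 76 miRNAs passed, 31 of them in the Dlk1-Dio3 cluster and all of these lower, and the cluster median was −0.68 (70 of 73 lower; adjusted p 6.12e-34, and adjusted p = 0.0456 with an estimated correlation). Muscle and leukocyte content, as far as these markers capture it, is thus an unlikely cause of the lower cluster, as the median moved further from 0 with them in the model. Chance is argued against for the count of 40, since 1 of 100 drawn splits gave as many (the real one; highest other 1). The same holds for the 76 with covariates (1 of 100; highest other 6). It also holds for the counts of 156 and 163 at an unadjusted p under 0.05 (1 of 100 each; highest others 79 and 97). These splits do not exclude chance, as the contrast was chosen after the data were seen. They test the counts and not each miRNA. For the counts of lists, chance stays open, with 4 (34 of 100 splits, highest other 6) and 2 with covariates (49 of 100, highest other 6). A hypothesis is tissue maturation, as the mice at week 3 may be older, but ages and dates are not given in the sources used here, and a batch difference between the times was not tested.

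The time contrasts of the diets share no library. At an unadjusted p under 0.05 there were 83 miRNAs in the control and 88 in the high-fat contrast, and 33 were in both, all in the same direction in both diets (14 higher, 19 lower), where independent lists give 3.99 and 2.57. Across the 558 miRNAs, which are not independent replicates, Spearman's rho was 0.594 and Pearson's r 0.587. Unrelated time effects in the diets are argued against by the splits of the 8 control libraries: 1 of 35 gave as many shared miRNAs (the real one; highest other 16), although the highest other rho was 0.565. A shared batch of all day 1 or all week 3 samples could give the same overlap.

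The diet contrast of the Dlk1-Dio3 mean was 0.75 log2 units higher at week 1 than at day 1. Chance may account for this, with an exact permutation p of 0.101 over 4900 regroupings of diet within time (adjusted p 0.666 over the lists and times).

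Some miRNAs with several genomic copies had few counts on the arm that the copies share. MiR-24-3p had 184 counts in all libraries, against 330702 for its copy-specific arms. A hypothesis is that some of the reads with several genomic matches were left uncounted. Over miRNAs with several copies the median log2 ratio of the shared arm to the copy-specific arms was 3.07 (26 miRNAs), against 5.13 for the larger to the smaller arm of 288 single-copy miRNAs, with a permutation p of 0.0728 that leaves it open. This comparison is tilted towards a low p whatever the cause, because a ratio of larger to smaller arm cannot be negative. In 8 of the 26 the shared arm was below the copy-specific arms. Other shared arms held many counts, such as miR-103-3p (724916, against 262 for its copy-specific arms) and miR-92a-3p (561613 against 1175). These values argue against a loss of all reads with several genomic matches. The reference also places another miRNA gene over miR-24, so reads in overlapping features may have been lost there.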
